A study of Triticum aestivum with 24 samples.

How the data were processed

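The series measured RNA from leaves of wheat seedlings in 24 libraries, 3 in each of 8 groups. Seedlings grew in soil tanks given medium with 5 mM nitrate and were then left without water until the soil was dry. The groups are well-watered plants, plants after drought, and plants rewatered for 3 h, 1 d or 5 d with medium holding 0 or 5 mM nitrate. Total RNA was enriched for polyadenylated RNA with oligo(dT) beads and reverse-transcribed with random primers, and libraries were amplified and circularised. The labels state no strand marking, batch or date, and do not say whether a library came from one plant or from a pool. Group and replicate number were taken from the sample names.

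Per the labels, the authors used HISAT and Bowtie2, whose versions are not given in the sources used here; neither is the genome build. The authors' deposited table has 82104 genes and 180 columns. Its deposited read counts are expected counts, which the authors estimated per gene and deposited without scaling. Between 32.28% and 41.11% of the values of a library were not whole within a tolerance of 1e-06, and they were rounded to whole numbers here. The authors' FPKM values were read as FPKM and used only to derive gene lengths, on which no value in the text rests. The log2 fold changes deposited by the authors, and the DESeq2 q-values deposited beside them (adjusted p-values), were used only as a comparison with the tests made here. The table gives a product name for 43700 genes (53.2%), and every gene name in the text is that product text. Positions of genes were not used; the chromosome is the part of the identifier that follows TraesCS.

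Library totals ranged from 13674888 to 15844027 counts, a ratio of 1.16. The main test was edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 51764. Libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 24 libraries with 1 mean per group. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, over all genes tested in a comparison. Whether the effect of nitrate differed between times was tested by an F test of the interaction, over all 3 times together and by pairs of times. Levels in the text are CPM (counts divided by TMM-scaled library size), as mean ± SD over the 3 libraries of a group, and fold changes come from the model.

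Gene lists were fixed before the data were examined, as 32 sets of words. The words were matched against all protein names that the table gives for a gene, so a member can bear another product name. The photosystem list includes members that the plastid encodes, which were left out only where the text says so. Also fixed beforehand were the comparisons, the main test, most alternatives and the rule that chose named genes. For drought and for nitrate, that rule took the 5 product names with the largest change each way among called genes with a mean of at least 1 CPM and no overlap between the libraries compared, each stood for by the gene with the smallest p that bears it. It also took, in each list, the called members with the smallest p and with the highest level, or, where none was called, the member with the highest level. The other comparisons took 3 product names each way. Lists with at least 5 tested genes were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. For each list the count of genes past the threshold is also given adjusted over the list alone. Genes at least 2-fold higher or lower in drought than in well-watered plants formed a pair of further lists, drought-raised and drought-lowered genes. These were chosen on libraries of this series, though not on the rewatered libraries in which they were tested.

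Where a group held 0 counts, the fold is a lower bound computed against 3 counts over the group. Where it held 1 to 3 counts, the ratio of counts is given with its exact (Clopper-Pearson) counting interval at a confidence level of 0.95. Such intervals and bounds cover counting error only. Close copies of a gene on the A, B and D genomes share reads, so a value for 1 copy is uncertain.

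The pipeline was tested on 8 sets of simulated data, with 100 genes changed at each of 2 sizes for each time and, for each gene, the same spread in all groups. At a 4-fold change 83.4%, 82.4% and 90.8% of changed genes were recovered for nitrate at 3 h, 1 d and 5 d. At a 2-fold change these shares were 41.4%, 42.5% and 48.8%. The share of edgeR calls that were false was 3.9% and 3.4% at 3 h and 1 d and 14.3% (9.6 to 17.9) at 5 d, above the 5% aimed for. For DESeq2, run on 1 of these sets, it was 9.8%, 14% and 26.2%. The real groups differed in spread, and the number of genes that truly changed in them is unknown. A share of false calls depends on both, so these shares need not hold for the real calls.

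The alternatives were RLE scaling, library totals without further scaling, no filter on low counts, a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, a fit of only the libraries compared, a replicate block, each library left out in turn, an estimated inter-gene correlation, and drought lists at other fold minimums. After seeing the data, limma-voom with library weights, lists without products that matched by spelling only, a fit without the 2 libraries that stood apart at 5 d, and comparisons of 3 h and 1 d of rewatering with well-watered plants were added. Product families were tested in place of KEGG pathways, which the table does not name. The replicate numbers did not pair the libraries: residuals of libraries with the same number correlated across genes between −0.532 and 0.334. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.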

Results

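Gene expression was measured by RNA sequencing in leaves of wheat seedlings that were kept watered, exposed to drought, or rewatered after drought with medium holding 0 mM nitrate (without nitrate) or 5 mM nitrate (with nitrate). The title of the series asks how nitrogen affects wheat during drought and recovery. Each of the 8 groups, well-watered, drought, and rewatered for 3 h, 1 d or 5 d at either nitrate level, has 3 libraries, so n = 3 for every mean ± SD given. Library totals lay between 13674888 and 15844027 counts, and 51764 of 82104 genes were tested. Nothing in the labels says whether the 3 libraries of a group come from separate plants, so the p-values measure only the spread between these samples. The labels give no well-watered or drought group matched in time to the rewatered groups. Plant age and time of harvest therefore cannot be told apart from rewatering in comparisons with either.

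On the first principal component, with 64% of the variance of log2 CPM, the well-watered libraries averaged 308 ± 8.6 and the drought libraries −73.9 ± 16.1. Libraries rewatered for 3 h and 1 d lay on the far side of drought, at −158.2 ± 4.5 and −156.1 ± 11.4 without nitrate and −128.4 ± 5.2 and −126.9 ± 15.7 with it. Those rewatered for 5 d lay between drought and well-watered, at 129.4 ± 86.4 without nitrate and 206.1 ± 64.9 with it. Within both 5 d groups 1 library stood apart, toward drought: replicate 2 without nitrate at 30 (the others at 171.9 and 186.4) and replicate 1 with nitrate at 131.2 (the others at 242.4 and 244.6). On the second component, with 15.4% of the variance, the 5 d groups lay at −113.2 ± 35.2 without and −126 ± 19.1 with nitrate. Drought lay at 24.2 ± 7.1 and well-watered at 169.3 ± 8.5, so the 5 d groups were not between them there.

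**Figure D1:**
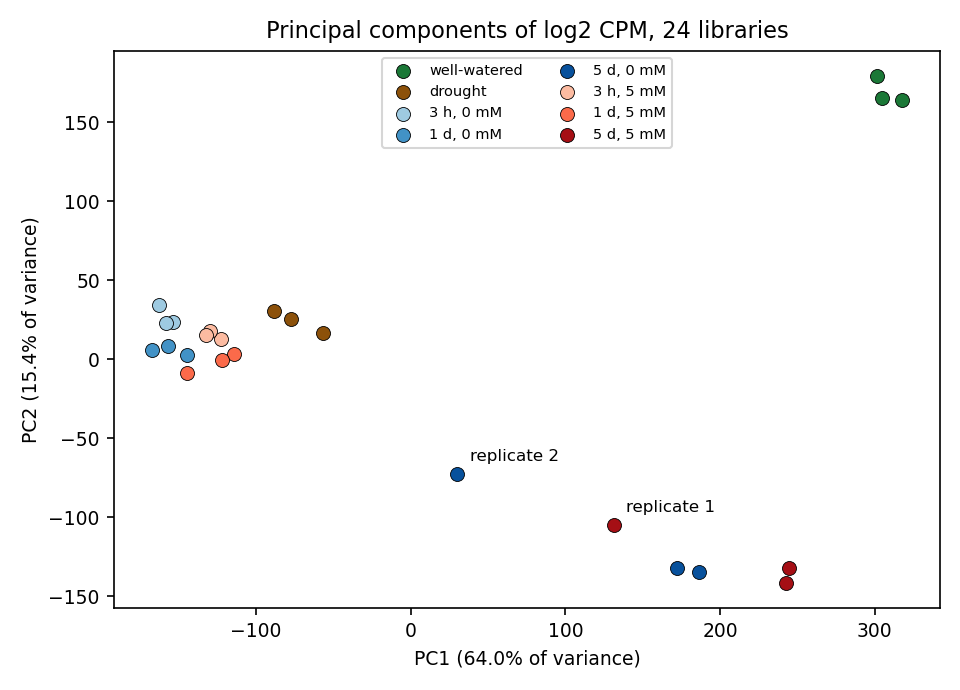
Each point is 1 of the 24 libraries, placed by its scores on the first and second principal components of log2 CPM, coloured by group. Libraries of 3 h and 1 d of rewatering lie near and beyond the drought libraries, and the 5 d libraries spread between 30 and 244.6 on the first component.

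Drought lowered the transcripts of photosynthesis. Of 109 tested genes for photosystems and light harvesting 81 fell and 0 rose (83 and 0 adjusted over the list alone), and of 34 Calvin cycle genes 30 fell and 0 rose (also 30 and 0 adjusted over the list alone). TraesCS5A02G165400, a Rubisco small subunit and so part of the enzyme that fixes carbon dioxide, fell 221-fold, from 1130 ± 74.7 to 5.08 ± 2.86 CPM (log2 −7.78, SE 0.69, adjusted p = 6.68e-09). The photosystem II 10 kDa polypeptide TraesCS6D02G340700 fell 11-fold, from 2220 ± 182 to 202 ± 22 CPM. Among 27 chlorophyll synthesis genes 19 fell and 0 rose, with the same numbers adjusted over the list alone. One of them, the protochlorophyllide oxidoreductase TraesCS1A02G171000, which acts at the light-dependent step, went from 61.9 ± 10 to 1.45 ± 0.827 CPM. The median log2 change was −4.83 for the photosystem list (−4.09 with 14 members at 0 in one group set to their bound), −6.26 for the Calvin cycle and −1.2 for chlorophyll synthesis. Against other genes these lists were lower at adjusted p = 1.41e-13, 8.28e-10 and 0.000382, but not with an estimated correlation (adjusted p = 0.477, 0.477 and 0.493 with an estimated correlation).

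Genes for ribosomal proteins also fell in drought, 93 of 99 cytosolic and 40 of 52 plastid ones, against 0 and 2 that rose; adjusted over the list alone the numbers were the same. The 60S ribosomal protein L6 gene TraesCS6D02G180100 fell 7.12-fold, from 21 ± 1.78 to 2.93 ± 0.688 CPM. The medians were −1.23 for both lists (adjusted p = 1.4e-11 and 7.28e-05; adjusted p = 0.493 and 0.477 with an estimated correlation). Of 26 autophagy genes, which serve the breakdown of cell contents in the vacuole, 22 rose and 0 fell, also adjusted over the list alone; their median was 1.26. Autophagy-related protein 9, TraesCS4D02G224800, rose 5.63-fold to 70.1 ± 9.97 CPM. The list stood above other genes at adjusted p = 2.24e-08 (adjusted p = 0.477 with an estimated correlation). Of 12 genes for chlorophyll breakdown and senescence, mostly senescence-domain and staygreen proteins, 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.039; adjusted p = 0.527 with an estimated correlation). The staygreen protein TraesCS5D02G325900 rose 5.01-fold to 645 ± 129 CPM.

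Genes named for their rise in drought included dehydrins and an enzyme of abscisic acid synthesis. The dehydrin TraesCS6D02G332900, of a family that protects dehydrating cells, rose 1960-fold, from 1.09 ± 0.428 to 2150 ± 380 CPM, and the dehydrin TraesCS5D02G379300 from 1 count over the well-watered group to 113 ± 29.5 CPM, a ratio of 6340 (1140 to 251000). The Rab protein TraesCS6B02G383500 rose 2220-fold to 3570 ± 444 CPM and the AAA domain protein TraesCS3D02G159200 4410-fold, from 0.0728 ± 0.0845 to 352 ± 28.7 CPM. The latter had only 4 counts over the well-watered group, so the size of its fold is uncertain. The 9-cis epoxycarotenoid dioxygenase TraesCS5B02G375900, a key enzyme of abscisic acid synthesis, rose 312-fold to 404 ± 105 CPM. Of 42 genes for osmolyte synthesis 23 rose and 7 fell, also adjusted over the list alone (adjusted p = 7.28e-05; adjusted p = 0.477 with an estimated correlation). Among them the delta-1-pyrroline-5-carboxylate synthase TraesCS3D02G357200, of proline synthesis, went from 2.75 ± 2.13 to 401 ± 83.5 CPM. The dehydrin and LEA list itself was mixed, with 5 of 10 genes higher and 4 lower, also adjusted over the list alone (adjusted p = 0.0412; adjusted p = 0.477 with an estimated correlation). The fixed abscisic acid list, 33 genes of which most are HVA22-like proteins, had 15 higher and 8 lower, also adjusted over the list alone, and a median of 0.22 (adjusted p = 0.0412; adjusted p = 0.477 with an estimated correlation).

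Genes of nitrogen and sugar metabolism moved as well. Of 6 nitrate reductase genes, the enzyme that reduces nitrate to nitrite, 5 rose, also adjusted over the list alone (adjusted p = 0.0412; adjusted p = 0.493 with an estimated correlation); TraesCS6D02G020700 rose 14-fold, from 2.78 ± 0.563 to 39 ± 7.37 CPM. The high-affinity nitrate transporter TraesCS6D02G193200 rose 11.5-fold to 1.95 ± 0.412 CPM. Among 32 genes of ammonium assimilation 10 rose and 11 fell, also adjusted over the list alone: the glutamine synthetase TraesCS4A02G063800 rose 37.4-fold to 813 ± 45.2 CPM, while TraesCS2B02G528300, also a glutamine synthetase, fell 51.3-fold, from 477 ± 40.5 to 9.26 ± 3.05 CPM. The peptide transporter PTR5 copies differed in the same way, TraesCS3D02G056300 rising 4.51-fold and TraesCS3A02G056400 falling 3.41-fold. Of 127 starch and sucrose genes 63 rose and 30 fell, also adjusted over the list alone (adjusted p = 0.00231; adjusted p = 0.374 with an estimated correlation), and the sucrose synthase TraesCS4A02G140000 rose 56.7-fold to 623 ± 61.7 CPM. Of 70 cell wall genes 31 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.00238; adjusted p = 0.493 with an estimated correlation), with the xyloglucan endotransglucosylase TraesCS2D02G431500 up 80.9-fold to 1630 ± 322 CPM. Their median was 1.22, or 0.53 with 13 members at 0 in one group set to their bound. The NAC factor TraesCS5B02G142100 rose 131-fold to 251 ± 49.3 CPM, 1 of 90 NAC genes of 189 that rose against 53 that fell, also adjusted over the list alone (adjusted p = 0.0204; adjusted p = 0.477 with an estimated correlation). Falls to 0 counts over the drought group were seen in TraesCS7D02G057000, a nucleoside phosphorylase domain protein, at least 552-fold lower, and the benzoxazinoid glucoside beta-glucosidase TraesCS2B02G600200, at least 389-fold lower. The peroxidase TraesCS2B02G278500 fell 38.1-fold, from 19.4 ± 2.29 to 0.498 ± 0.133 CPM.

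In all, 17450 genes rose and 18458 fell in drought, 69.4% of those tested, and 12144 and 14281 of them at least 2-fold. Of markers of other leaf cells, 33 of 101 epidermis and cuticle genes were higher and 19 lower, with a median of 0 (the same counts adjusted over the list alone; adjusted p = 0.606). Vascular and lignin genes leaned downward, with 39 of 87 lower and 16 higher (39 and 15 adjusted over the list alone) and a median of −1.33, or −1.27 with members at 0 in one group at their bound; the list call was missed (adjusted p = 0.171). Library totals in place of TMM shift the log2 change of every gene by −0.295 and give 14291 up and 22127 down, and changes are given relative to the TMM scale.

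**Figure D2:**
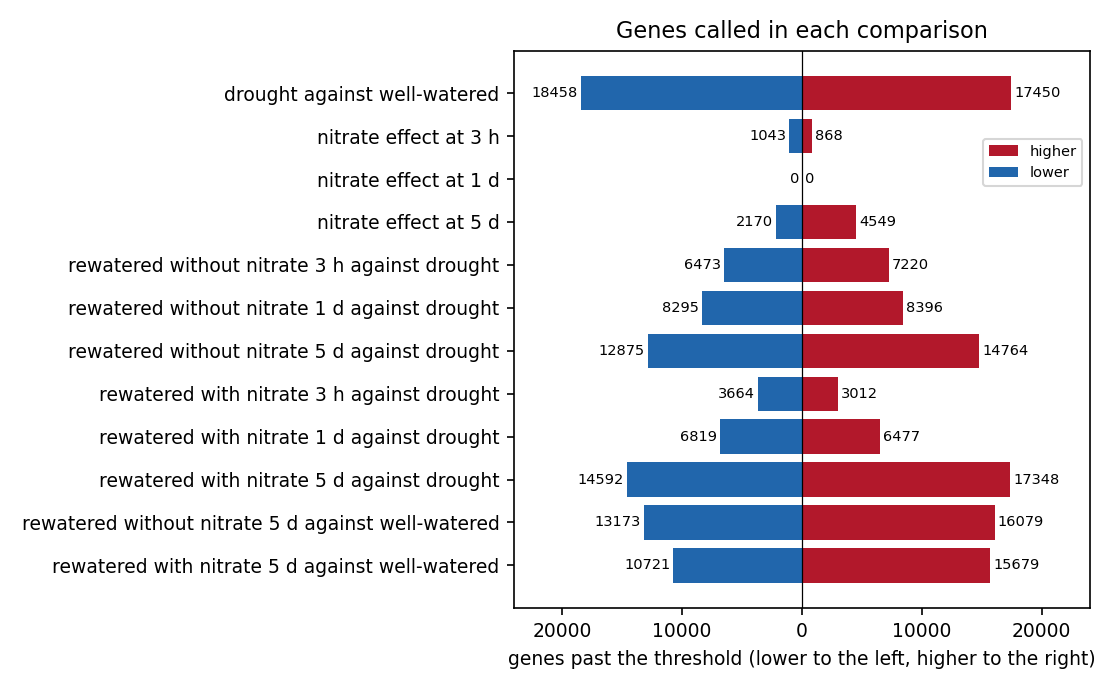
Bars give the number of genes called at an adjusted p under 0.05 by edgeR in each of 12 comparisons, higher to the right and lower to the left, out of 51764. The count for nitrate is 1911 at 3 h, 0 at 1 d and 6719 at 5 d.

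After 3 h or 1 d of rewatering few transcripts of photosynthesis were called as changed from drought. Without nitrate, 1 of 109 photosystem genes rose and 1 fell after 3 h (the same adjusted over the list alone), and 1 rose and 2 fell after 1 d (0 and 1 adjusted over the list alone). With nitrate 0 rose and 2 fell after 3 h (0 and 1 adjusted over the list alone) and 0 rose and 3 fell after 1 d (0 and 2 adjusted over the list alone). The photosystem medians leaned downward, at −0.57 and −0.61 without and −0.57 and −0.29 with nitrate for 3 h and 1 d, or −0.34, −0.56, −0.51 and −0.22 with members at 0 in one group at their bound. The list call was missed in each (adjusted p = 0.0809, 0.169, 0.0925 and 0.276). None of 34 Calvin cycle genes was called in these 4 edgeR comparisons, also adjusted over the list alone. The Rubisco small subunit TraesCS5A02G165400 stayed low, at 4.77 ± 2.21 CPM after 3 h and 5.94 ± 1.57 CPM after 1 d without nitrate (adjusted p = 0.938 and 0.824 against drought). The dehydrin TraesCS6D02G332900 rose further, 2.69-fold to 5780 ± 192 CPM after 3 h without nitrate, and the nitrate reductase TraesCS6D02G306000 rose 4.61-fold to 15.3 ± 8.03 CPM.

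Heat shock protein genes, which encode chaperones, were higher after 3 h and 1 d of rewatering than in drought. Without nitrate 27 of 32 rose at 3 h and 24 at 1 d, with 0 falling (27 and 26 up adjusted over the list alone). With nitrate 13 rose at 3 h and 24 at 1 d, again with 0 falling (19 and 25 up adjusted over the list alone). The small heat shock protein TraesCS3B02G131200 rose 6.18-fold at 3 h without nitrate, from 2.83 ± 1 to 17.6 ± 0.267 CPM, and TraesCS4B02G211700 rose 9.44-fold at 1 d with nitrate, to 23.1 ± 4.78 CPM. The Clp R domain protein TraesCS3A02G274400, outside that list, rose 13.4-fold and 7.39-fold at 3 h without and with nitrate. The list's medians were 0.97, 0.82, 0.53 and 0.72 in the order 3 h and 1 d without nitrate and 3 h and 1 d with it (adjusted p = 2.44e-22, 1.54e-14, 2.48e-11 and 9.3e-17). With an estimated correlation the adjusted p was 0.0127, 0.0786, 0.177 and 0.0447, so the call holds at 3 h without and at 1 d with nitrate. Of 99 cytosolic ribosomal genes 43 fell and 1 rose at 3 h without nitrate (51 and 1 adjusted over the list alone; adjusted p = 3.32e-08; adjusted p = 0.809 with an estimated correlation), as against 2 that fell and 1 that rose with nitrate (1 and 0 adjusted over the list alone; adjusted p = 0.353). In the same comparison without nitrate 31 of 101 epidermis and cuticle markers fell and 5 rose (32 and 5 adjusted over the list alone; adjusted p = 0.000103; adjusted p = 0.809 with an estimated correlation).

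The counts against drought were 7220 up and 6473 down at 3 h and 8396 up and 8295 down at 1 d without nitrate, and 3012 up and 3664 down at 3 h and 6477 up and 6819 down at 1 d with nitrate. These splits depend on the scaling: library totals shift log2 changes by −0.322, −0.369, −0.181 and −0.24 in that order and give 3153 up and 13770 down, 3406 up and 16221 down, 1405 up and 6084 down, and 3218 up and 11188 down. For 3 h with nitrate, 6676 genes in all, the count was 3799 without drought replicate 3 and 4255 and 4363 without replicates 2 and 3 of 3 h with nitrate.

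After 5 d photosynthesis genes had risen strongly from drought. Calvin cycle genes rose in 30 of 34 cases without and 31 with nitrate, with 0 falling (the same adjusted over the list alone). Photosystem genes rose in 70 and 84 of 109 cases and fell in 2 and 2 (73 and 85 up and 2 and 2 down adjusted over the list alone). The Rubisco small subunit TraesCS5A02G165400 rose 187-fold to 957 ± 643 CPM without and 553-fold to 2830 ± 1470 CPM with nitrate, with a wide spread between libraries. The photosystem II 10 kDa polypeptide TraesCS6D02G340700 rose 1.69-fold to 341 ± 79.7 and 3.14-fold to 634 ± 178 CPM. Of 26 autophagy genes 24 fell in both, and 0 rose (the same adjusted over the list alone). The expansin TraesCS1B02G310300, of a family that loosens cell walls, was at least 299-fold higher without nitrate, at 20.4 ± 22.1 CPM. The carboxypeptidase TraesCS3B02G384800 fell 25.1-fold there, from 125 ± 17.2 to 4.98 ± 1.89 CPM. The list medians without and with nitrate were 6.13 and 8.64 for the Calvin cycle (adjusted p = 2.97e-15 and 2.94e-18; adjusted p = 0.32 and 0.258 with an estimated correlation), 3.78 and 5.56 for photosystems (adjusted p = 3.99e-12 and 2.43e-14; adjusted p = 0.361 and 0.324 with an estimated correlation) and −1.06 and −1.17 for autophagy (adjusted p = 2.08e-15 and 1.13e-14; adjusted p = 0.233 and 0.208 with an estimated correlation). The photosystem medians are 3.62 and 5.45 with members at 0 in one group at their bound. Vascular and lignin markers rose too, in 62 and 61 of 87 cases with 5 and 6 falling (66 and 64 up and 7 and 7 down adjusted over the list alone; adjusted p = 7.57e-08 and 5.21e-08; adjusted p = 0.32 and 0.258 with an estimated correlation). Epidermis and cuticle markers rose in 61 and 44 of 101 cases and fell in 8 and 13 (64 and 43 up and 8 and 13 down adjusted over the list alone), with medians of 1.46 and 0.76 (adjusted p = 1.15e-06 and 0.014; adjusted p = 0.332 and 0.491 with an estimated correlation). Against drought 14764 genes rose and 12875 fell without nitrate, and 17348 rose and 14592 fell with it; library totals shift log2 changes by 0.328 and 0.236 and give 21013 up and 7740 down, and 20890 up and 10947 down.

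Against well-watered plants, which the labels do not match to them in time, the 5 d leaves had higher cell wall transcripts. Of 70 genes for cell wall expansion 61 were higher and 3 lower without nitrate and 57 higher and 2 lower with it (the same adjusted over the list alone), with medians of 3.76 and 4.28, or 3.7 and 4.23 with members at 0 in one group at their bound. The xyloglucan endotransglucosylase TraesCS7A02G427000 was 523-fold higher without nitrate, at 145 ± 41.2 against 0.268 ± 0.138 CPM. The tests gave adjusted p = 2.1e-12 and 9.56e-13, and adjusted p = 0.416 and 0.232 with an estimated correlation. Photosystem genes were lower in 51 and higher in 4 of 109 cases without nitrate (50 and 4 adjusted over the list alone), and lower in 36 and higher in 18 with it (the same adjusted over the list alone); the median of the latter, −0.14, became 0.06 without members that matched by spelling only or that the plastid encodes. The tests gave adjusted p = 9.13e-06 and 0.0247, and adjusted p = 0.815 and 0.885 with an estimated correlation. The photosystem II 10 kDa polypeptide TraesCS6D02G340700 remained 6.51-fold lower without and 3.5-fold lower with nitrate. Calvin cycle genes were higher in 2 and lower in 8 of 34 cases without nitrate (2 and 7 adjusted over the list alone), and higher in 23 and lower in 1 with it (23 and 2 adjusted over the list alone). Neither list call passed the preset test (adjusted p = 0.119 and 0.12). All 6 nitrate reductase genes with nitrate and 4 of 6 without were higher, also adjusted over the list alone (adjusted p = 5.8e-05 and 0.0273; adjusted p = 0.27 and 0.815 with an estimated correlation). The dehydrin TraesCS5D02G379300 stayed up at 183 ± 74.2 and 82.2 ± 38.5 CPM, ratios of 10100 (1810 to 399000) and 4630 (831 to 183000) to the 1 count in the well-watered group. The 3-ketoacyl-CoA synthase TraesCS7D02G035700, of wax and fatty acid elongation, had 0 counts in both 5 d groups against 16.3 ± 2.98 CPM, at least 305-fold and 309-fold lower. Epidermis and cuticle markers were higher in 62 and 56 of 101 cases and lower in 9 and 13 (67 and 60 up and 9 and 13 down adjusted over the list alone; adjusted p = 2.84e-05 and 0.00294; adjusted p = 0.815 and 0.855 with an estimated correlation). Vascular and lignin markers were higher in 42 and 52 of 87 cases and lower in 13 and 12 (42 and 54 up and 13 and 12 down adjusted over the list alone), with medians of 1.42 and 1.76, against 2.34 and 1.69 for the epidermis list (adjusted p = 0.0273 and 0.000579; adjusted p = 0.87 and 0.855 with an estimated correlation). In all 16079 genes were higher and 13173 lower without nitrate, and 15679 and 10721 with it; library totals give 16403 and 12212, and 14559 and 11512.

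**Figure D3:**
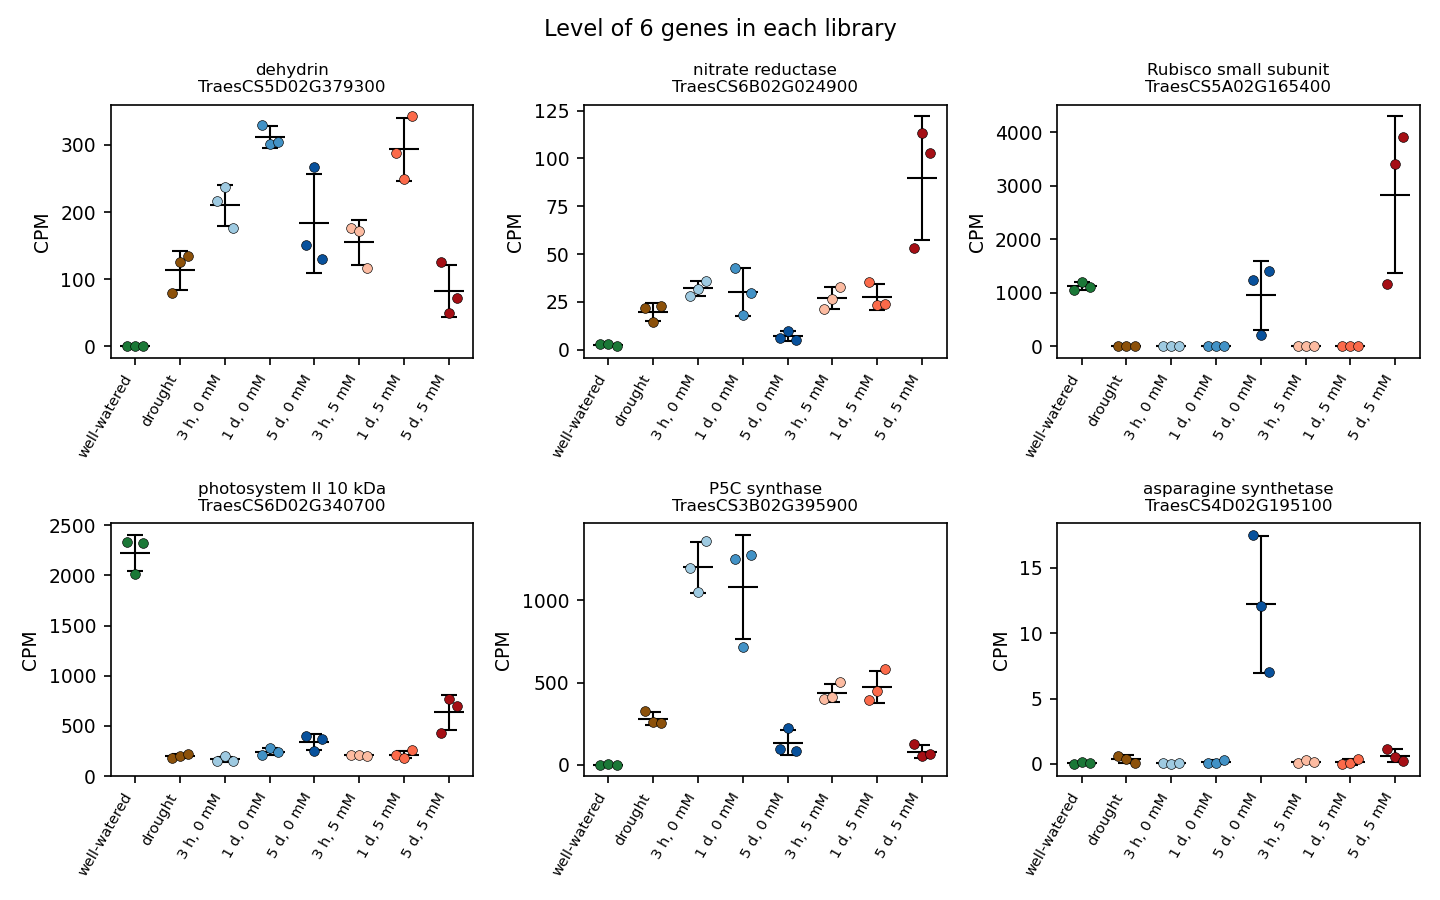
Points are the CPM of 6 genes in each library, with the mean and SD of each group of 3 libraries. The Rubisco small subunit TraesCS5A02G165400 falls from 1130 CPM in well-watered leaves to 5.08 in drought and returns to 957 and 2830 at 5 d without and with nitrate, where the libraries spread widely.

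Nitrate in the rewatering medium, after 3 h, came with higher ribosomal protein transcripts and lower heat shock transcripts. Of 99 cytosolic ribosomal genes 15 rose and 0 fell (62 and 0 adjusted over the list alone), with a median log2 change of 0.55. The 40S ribosomal protein SA gene TraesCS4B02G299100 rose 2.06-fold, to 20.2 ± 7.48 from 9.8 ± 1.03 CPM. Of 52 plastid ribosomal genes 4 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.45), among them TraesCS5D02G121600 at 42.6 ± 11.7 against 26 ± 1.48 CPM. Of 32 heat shock genes 7 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of −0.5; the Hsp70-Hsp90 organizing protein TraesCS6D02G221000 fell 1.65-fold, from 71.1 ± 8.65 to 43.1 ± 0.272 CPM. The tests of these lists gave adjusted p = 2.95e-27, 7.19e-05 and 2.56e-12, and adjusted p = 0.6, 0.659 and 0.159 with an estimated correlation. Epidermis and cuticle markers moved with them, 9 of 101 up and 1 down (23 and 1 adjusted over the list alone), with a median of 0.48, or 0.42 with members at 0 in one group at their bound (adjusted p = 1.16e-06; adjusted p = 0.6 with an estimated correlation). They include the lipid-transfer protein TraesCSU02G251500, at 96.3 ± 38.7 with and 39.8 ± 6.4 CPM without nitrate.

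Single genes of nitrogen and stress metabolism were also called at 3 h, in calls that hinge on the libraries kept. Of the 20 genes named for nitrate at 3 h, 8, 16 and 7 were called without replicates 1, 2 and 3 without nitrate, and 7, 8 and 20 without those with nitrate. The nitrate reductase TraesCS6D02G306000 was lower with nitrate, at 2.44 ± 0.706 against 15.3 ± 8.03 CPM (6.26-fold, log2 −2.65, SE 0.58, adjusted p = 0.0164), the only call among 6 such genes (2 adjusted over the list alone; list adjusted p = 0.00748; adjusted p = 0.6 with an estimated correlation). The high-affinity nitrate transporter TraesCS6D02G193200 was at 1.84 ± 0.154 with and 2.31 ± 0.496 CPM without nitrate (adjusted p = 0.68). The glutamine synthetase TraesCS6B02G327500 rose 1.63-fold, to 320 ± 31.2 from 197 ± 11.2 CPM; 3 of 32 ammonium assimilation genes rose and 0 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0301; adjusted p = 0.6 with an estimated correlation). Without members that matched by spelling only, that list gave adjusted p = 0.0985. The delta-1-pyrroline-5-carboxylate synthase TraesCS3B02G395900 fell 2.74-fold, from 1200 ± 155 to 438 ± 55.2 CPM. The SPX domain protein TraesCS2D02G177100, of a family that senses phosphate status, fell 11.3-fold, from 3.73 ± 2.73 to 0.325 ± 0.0439 CPM, 1 of 8 of 103 phosphate starvation genes that fell, with 0 rising (11 and 0 adjusted over the list alone; adjusted p = 0.123). Among the changes chosen for size, the HTH myb-type protein TraesCS7D02G295400 fell 12.1-fold, from 15.9 ± 2.25 to 1.3 ± 0.146 CPM, and HY5, TraesCS6D02G167800, a transcription factor of light signalling, fell 9.71-fold. The JmjC domain protein TraesCS7D02G244500 rose 7.66-fold, from 0.605 ± 0.188 to 4.71 ± 0.47 CPM, and the calcium-transporting ATPase TraesCS4B02G007200 7.68-fold, to 1.97 ± 0.751 CPM.

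At 3 h 868 genes rose and 1043 fell with nitrate. Library totals shift log2 changes by 0.141 and turn this split to 1692 up and 540 down. The total of 1911 was 489, 1259 and 470 without replicates 1, 2 and 3 of 3 h without nitrate, and 407, 401 and 3376 without replicates 1, 2 and 3 of 3 h with it; it was 3722 in a fit of these 6 libraries and 3243 by DESeq2 (9.8% of its 3 h calls were false in 1 set of simulated data).

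After 1 d, edgeR called 0 genes for nitrate, with a lowest adjusted p of 0.146, and 4029 of 51764 genes had an unadjusted p under 0.05. DESeq2 called 33 genes (14% of its 1 d calls were false in 1 set of simulated data), limma-voom with library weights 1854, a fit of the 6 libraries alone 3, and the authors' deposited values 126. Those 3 genes, named after their values were seen, were lower with nitrate: TraesCS4B02G120400 and TraesCS4D02G118500, both serine/threonine protein kinases, at log2 −1.75 (SE 0.19) and −2.22 (SE 0.25), and TraesCS5A02G317100, with no product name, at log2 −1.67 (SE 0.17), all with adjusted p = 0.0129 there. The count was 3 without replicate 2 of 1 d without nitrate and 6 without replicate 3 of 1 d with nitrate. As lists, cytosolic ribosomal genes again stood higher with nitrate (median 0.37, adjusted p = 2.68e-22; adjusted p = 0.686 with an estimated correlation) and autophagy genes lower (median −0.28, adjusted p = 4.14e-09; adjusted p = 0.538 with an estimated correlation), with 0 of 99 and 0 of 26 members called by edgeR, also adjusted over the list alone. Phosphate starvation genes had a median of −0.16, with 0 of 103 called (8 lower adjusted over the list alone; adjusted p = 2.17e-05; adjusted p = 0.457 with an estimated correlation). The ribosomal protein S3a gene TraesCS4D02G260400 was at 104 ± 17.4 against 89.8 ± 7.51 CPM (adjusted p = 0.714) and the autophagy-related protein TraesCS2B02G491200 at 400 ± 115 against 548 ± 49.9 CPM (adjusted p = 0.585). The nitrate reductase TraesCS6D02G020700 was at 47.6 ± 6.57 with and 45.6 ± 15 CPM without nitrate (adjusted p = 0.981). The Rubisco small subunit TraesCS5A02G165400 was at 6.24 ± 1.83 and 5.94 ± 1.57 CPM (adjusted p = 1). Library totals shift log2 changes by 0.129 at this time.

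After 5 d, leaves given nitrate had higher transcripts of photosynthesis and of nitrate reduction in the fit of all 24 libraries. Of 34 Calvin cycle genes 25 were called higher and 0 lower (31 and 0 adjusted over the list alone), of 109 photosystem genes 24 and 0 (55 and 1 adjusted over the list alone), and of 27 chlorophyll synthesis genes 11 and 0 (18 and 0 adjusted over the list alone). Their medians were 2.46, 1.25 and 0.93. The Rubisco activase B TraesCS4A02G177600, which keeps Rubisco active, was 22.2-fold higher, at 90 ± 66.7 against 4.02 ± 2.41 CPM, and the uroporphyrinogen decarboxylase TraesCS4A02G136400, of chlorophyll synthesis, 1.88-fold higher, at 111 ± 32.8 against 59 ± 7.34 CPM. The photosystem II 10 kDa polypeptide TraesCS6D02G340700 was 1.86-fold higher, at 634 ± 178 against 341 ± 79.7 CPM. Of 6 nitrate reductase genes 3 were higher and 0 lower (the same adjusted over the list alone): TraesCS6B02G024900 was 12.6-fold higher, at 89.8 ± 32.2 against 7.1 ± 2.55 CPM (log2 3.66, SE 0.34, adjusted p = 3.33e-05), and TraesCS6D02G020700 2.81-fold higher. The tests of these 4 lists gave adjusted p = 2.73e-18, 1.05e-09, 8.91e-09 and 2.48e-06, and adjusted p = 0.362, 0.416, 0.416 and 0.312 with an estimated correlation. These 5 d calls depend on the fit: 6719 genes were called in it (4549 up, 2170 down), but 0 by edgeR in a fit of only the 6 libraries compared, and none of the 22 genes named for this comparison was called there. In the fit of all libraries 14475 genes had an unadjusted p under 0.05, DESeq2 called 6913 (26.2% of its 5 d calls were false in 1 set of simulated data) and the authors' deposited values 1103.

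Genes of nitrogen assimilation, sulfate and sugar phosphate metabolism were among those 5 d calls. The ferredoxin-dependent glutamate synthase TraesCS2D02G132900 was 2.51-fold higher with nitrate, at 370 ± 136 against 147 ± 29.7 CPM. The asparagine synthetase TraesCS4D02G195100, which stores nitrogen in asparagine, was 18.7-fold lower, at 0.639 ± 0.481 against 12.2 ± 5.24 CPM. Of 32 ammonium assimilation genes 8 were higher and 3 lower (9 and 4 adjusted over the list alone; adjusted p = 0.103). Of 24 genes in the list of nitrate-response regulators and reductant supply 8 were higher and 0 lower (11 and 1 adjusted over the list alone; adjusted p = 3.46e-05; adjusted p = 0.362 with an estimated correlation). Most members of that list are dehydrogenases of the pentose phosphate pathway, which makes NADPH, such as the glucose-6-phosphate 1-dehydrogenase TraesCS2A02G067800, 3.81-fold higher at 14.3 ± 4.19 against 3.74 ± 0.763 CPM. Of 18 sulfate assimilation genes 9 were higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 0.00063; adjusted p = 0.312 with an estimated correlation), with the sulfate adenylyltransferase TraesCS2B02G046500 4.68-fold higher. The heat shock protein 70 gene TraesCS5B02G087700 was 1.76-fold lower, at 173 ± 16.6 against 305 ± 8.01 CPM, and the dehydrin TraesCS5D02G379300 2.22-fold lower, at 82.2 ± 38.5 against 183 ± 74.2 CPM. Of 189 NAC genes 25 were lower and 8 higher (31 and 11 adjusted over the list alone; adjusted p = 0.0111; adjusted p = 0.416 with an estimated correlation). Epidermis and cuticle markers moved with these lists, 13 of 101 lower and 0 higher (24 and 1 adjusted over the list alone; median −0.36; adjusted p = 3.46e-05; adjusted p = 0.416 with an estimated correlation), and include the lipid-transfer protein TraesCS3B02G064100, at 31.2 ± 3.79 against 99 ± 28.5 CPM.

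The 5 d count moved with the libraries kept. It was 3018 without replicate 2 of 5 d without nitrate, 12565, 1789 and 2882 without replicates 1, 2 and 3 of 5 d with nitrate, and 8925 without both libraries that stood apart, a setting chosen after seeing the data in which all 22 named genes were called. A wrong split of the 6 libraries, with those 2 on the same side, called 8719. In simulated data 14.3% of 5 d calls by edgeR were false. There the spread of each gene was equal in all groups. In the real libraries the median SD of log2 CPM over genes was 0.269 and 0.28 at 5 d without and with nitrate. In the other groups it was 0.174 to 0.216. The simulated share therefore need not hold for the real 5 d calls. Library totals turn the split to 3228 up and 3672 down.

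**Figure D4:**
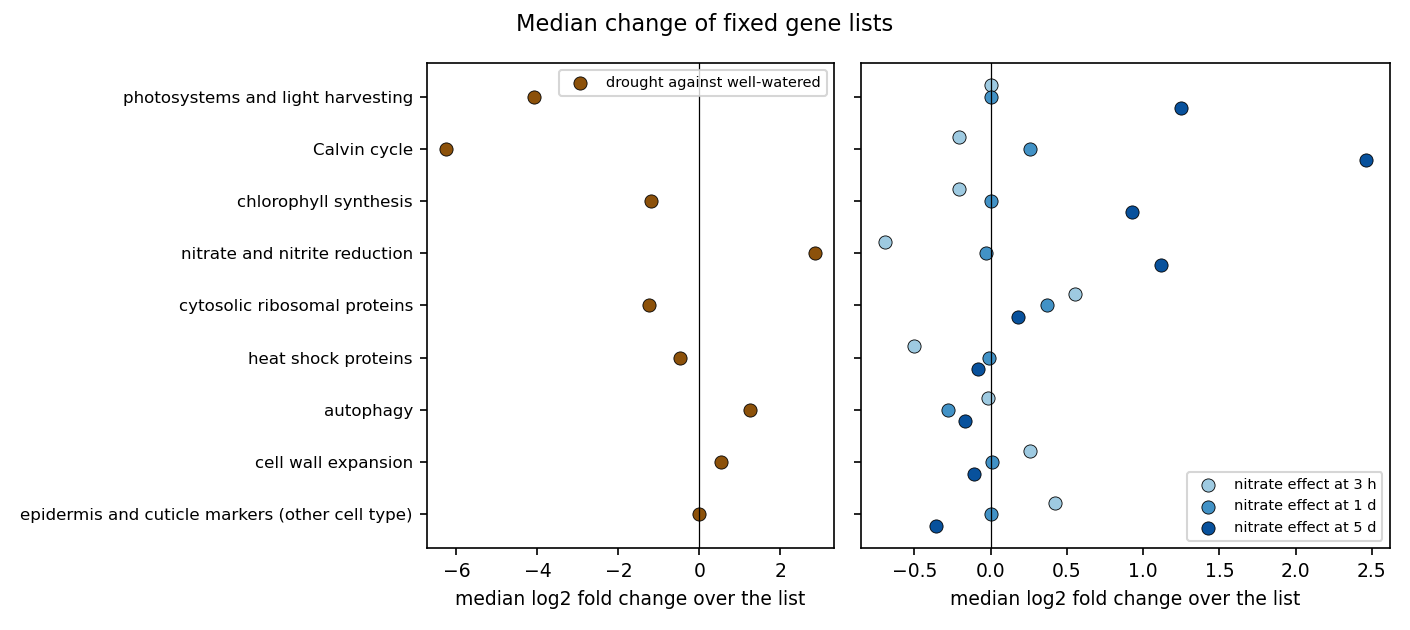
Points are the median log2 fold change of 9 fixed gene lists, members at 0 in one group set to their bound, for drought against well-watered on the left and for nitrate at 3 h, 1 d and 5 d on the right, on scales that differ. The Calvin cycle median is −6.26 in drought and 2.46 for nitrate at 5 d. No list call in these comparisons, drought or nitrate at any time, held with an estimated correlation.

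In the fit of all 24 libraries the effect of nitrate was called as different between times in 1335 genes. The nitrate reductase TraesCS6B02G024900 (12.6-fold higher at 5 d) was among them, with an adjusted p of 0.00026 for the difference between times, and so was TraesCS6D02G020700 (adjusted p = 0.0144), whereas for TraesCS6D02G306000, lower at 3 h, the difference missed the threshold (adjusted p = 0.0565). The catalase TraesCS4D02G322700, which breaks down hydrogen peroxide, was 1.61-fold lower with nitrate at 3 h, at 293 ± 43 against 471 ± 73 CPM, and 2.06-fold higher at 5 d, at 208 ± 48.1 against 101 ± 2.59 CPM (adjusted p = 0.00105 for the difference). The Rubisco activase TraesCS4A02G177600 and the Rubisco small subunit TraesCS5A02G165700, called at 5 d, did not differ between times by this test (adjusted p = 0.0722 and 0.303). By pairs of times 2122 genes differed between 5 d and 3 h, 379 between 5 d and 1 d, and 5 between 1 d and 3 h. Those 5, named after their values were seen, all had a more positive effect at 1 d: the Sec61 beta subunits TraesCS4D02G130200 and TraesCS4B02G135500 (log2 differences 2.25, SE 0.3, and 2.17, SE 0.32) and TraesCS5A02G219400, TraesCS1B02G432400 and TraesCS1B02G326800, which have no product name (3.12, 3.36 and 3.29). Most calls by pairs thus involve 5 d, where the nitrate effect itself was called in 0 genes in a fit of its 6 libraries. The share of false calls was not simulated for the difference between times. The count of 1335 was 620 in a fit of the 18 rewatered libraries and 2997 by DESeq2. Without replicates 1 and 3 of 3 h without nitrate it was 642 and 648, without replicates 1 and 2 of 3 h with nitrate 750 and 592, without replicate 2 of 1 d with nitrate 775, without replicate 1 of 5 d without nitrate 765, and without replicates 1, 2 and 3 of 5 d with nitrate 3945, 548 and 736.

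Genes that drought had changed leaned the other way with nitrate. The 12144 drought-raised genes had a median log2 nitrate effect of −0.11 at 3 h, −0.12 at 1 d and −0.28 at 5 d, and the 14281 drought-lowered genes 0.16, 0.17 and 0.34, while the median of all genes was 0. Of the 35908 genes called for drought, 60.6%, 64.3% and 71.8% had a nitrate effect pointing toward the well-watered level. The preset test gave adjusted p of 0.000324, 9.59e-08 and 1.93e-19 for the raised and 0.00026, 1.55e-06 and 1.95e-15 for the lowered genes. With an estimated correlation adjusted p = 0.405, 0.259 and 0.0677 for both lists, past the threshold at none of the times. The medians at 1 d and 5 d moved with the libraries kept. Without replicate 2 of 5 d without nitrate those at 5 d were −0.11 and 0.2, without replicate 1 of 5 d with nitrate −0.42 and 0.48, and without replicate 1 of 1 d with nitrate the lowered genes had 0.09 at 1 d. Other splits of the 6 libraries gave medians as far from 0 at 1 d and at 5 d, where 1 of them had 0.378 and −0.52. With library totals the raised genes had medians of 0.03 and 0.01 at 3 h and 1 d, still below the median of 0.12 over all genes.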

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

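The test without replicate 2 of 5 d without nitrate, the splits of the nitrate libraries within the fit of all 24 libraries, the counts without both libraries that stood apart at 5 d, limma-voom, and the comparisons of 3 h and 1 d of rewatering with well-watered plants, with their settings, were chosen after the data were seen; the other tests were planned.

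In the fit of all 24 libraries the effect of nitrate was called as different between times, by the test of the difference itself, in 1335 genes. By pairs of times 2122 genes differed between 5 d and 3 h, 379 between 5 d and 1 d, and 5 between 1 d and 3 h. The count thus rests mainly on 5 d, where the nitrate effect was called in 0 genes in a fit of its 6 libraries. In a fit of the 18 rewatered libraries, nitrate was reassigned within each time in 100 ways, the real one included. Only the real one reached its own count (620, highest other 110). Such reassignments remove any nitrate effect, also one that is equal at all times. They therefore cannot decide whether the effect differs between times, and they were not run for the count of 1335. Of the genes named for a nitrate effect 27 differed between times. Over all genes tested the share was 2.6%. The named genes were chosen from those called for nitrate in these same data, which favours a difference between times. Their number is therefore no further evidence. Those named at 3 h were TraesCS5A02G515900, a protein kinase (adjusted p = 0.00618), the JmjC protein TraesCS7D02G244500 (0.00634), the tryptophan synthase TraesCS5D02G447900 (0.0276), the HMA domain protein TraesCS2B02G077100 (0.0401), the calcium-transporting ATPase TraesCS4B02G007200 (0.0407), the HTH myb-type protein TraesCS7D02G295400 (0.00786), HY5 TraesCS6D02G167800 (0.00842), the TPR protein TraesCS4D02G183700 (0.00255), the Hsp70-Hsp90 organizing protein TraesCS6D02G221000 (0.0328), the 3-ketoacyl-CoA synthase TraesCS4D02G148300 (0.00623), the lipid-transfer protein TraesCSU02G251500 (0.000804) and the catalase TraesCS4D02G322700 (0.00105).

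Those named at 5 d were the nitrate reductases TraesCS6B02G024900 (adjusted p = 0.00026) and TraesCS6D02G020700 (0.0144), the protein kinase TraesCS4B02G107500 (0.000957), the MLO-like protein TraesCS2D02G081400 (0.0197), the asparagine synthetase TraesCS4D02G195100 (0.0402), the glutamine amidotransferase TraesCS4B02G194400 (0.0111), the BURP protein TraesCS3B02G314300 (0.00207), TraesCS6A02G106000, whose product name is plasminogen (0.0328), the gibberellin oxidase GA2ox3-1 TraesCS3A02G294000 (0.0443), the glutamate synthase TraesCS2D02G132900 (0.0018), the glucose-6-phosphate dehydrogenase TraesCS2A02G067800 (0.00297), the uroporphyrinogen decarboxylase TraesCS4A02G136400 (0.0336), the sulfate adenylyltransferase TraesCS2B02G046500 (0.018), the heat shock protein 70 TraesCS5B02G087700 (0.0101) and the lipid-transfer protein TraesCS3B02G064100 (0.00095).

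Of the fixed lists 13 differed in their nitrate effect between 5 d and 3 h by camera with the preset correlation. The adjusted p was 3.03e-11 for nitrate reductases, 3.75e-05 for nitrate-response regulators and reductant supply, 0.0027 for heat shock proteins, 0.000145 for photosystems, 1.52e-14 for the Calvin cycle, 1.35e-08 for chlorophyll synthesis and 0.0297 for chlorophyll breakdown. It was 9.77e-08 for cytosolic ribosomal proteins, 0.0157 for cell wall expansion, 4.21e-06 for sulfate assimilation, 0.0391 for WRKY factors, 0.0223 for NAC factors and 1.14e-11 for epidermis and cuticle markers. With an estimated correlation none of the 13 passed; the adjusted p was 0.0551 for nitrate reductases, 0.0611 for sulfate assimilation and at least 0.329 for the others.

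The first pattern weighed is the 0 genes called for nitrate at 1 d between 1911 at 3 h and 6719 at 5 d. The tables argue against lower depth, as library totals at 1 d were 1.02 times those at 3 h. They also argue against the shared fit having hidden as many genes at 1 d as were called at 3 h. A fit of the 6 libraries of 1 d alone called 3 genes, against 3722 in the same kind of fit at 3 h. The median SD of log2 CPM, without and with nitrate, was 0.188 and 0.206 at 1 d and 0.174 and 0.216 at 3 h. That kind of fit also called 0 at 5 d, where the SD was 0.269 and 0.28. A low count in it therefore does not show that no gene was hidden at 1 d. The highest count with 1 library left out was 6, against 401 to 3376 at 3 h. This argues against 1 deviating library having hidden as many genes at 1 d as were called at 3 h. Limma-voom with library weights called 1854 at 1 d, but also 10254 at 3 h and 8722 at 5 d. Its count thus does not single out a library at 1 d. A weaker effect of nitrate at 1 d is a hypothesis that stays open. The direct tests found 5 genes that differed between 1 d and 3 h and 379 between 5 d and 1 d. Limma-voom also called fewer genes at 1 d than at 3 h or 5 d. The 10 splits of the 6 libraries are too few for a share under 0.05, and the real and the highest other count were 0 and 0 (10 of 10 as large). At 3 h they were 1911 and 0 (1 of 10).

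The second pattern is the size of the nitrate count at 5 d. Replicate 2 without nitrate may account for part of it, as the count without it was 3018 against 6719; but it was also 1789 without replicate 2 with nitrate, and 8925 without both libraries that stood apart, so the fall is not particular to that library. Replicates that differ in how far they had recovered may account for it too: of genes called for drought 71.8% had a nitrate effect pointing toward well-watered, and so would a faster recovery with nitrate, which the design names and which stays open. Of the 10 splits, too few for a share under 0.05, 2 called as many genes, the highest other calling 8719. That split puts the 2 libraries that stood apart on the same side, which points to a structure of the samples other than nitrate.

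The third pattern is that leaves rewatered for 3 h and 1 d lay farther from well-watered than drought leaves, with 30945 and 30886 genes at least 2-fold away without nitrate against 26425. The tables argue against TMM scaling as its cause, as library totals gave 32471 at 1 d without nitrate against 27007 in drought. They argue against a few abundant genes taking the counts, as without the 100 most abundant genes the counts were 30633 and 26218. Continued decline of leaves after rewatering and differences in sampling time were not tested.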

How the results depend on the processing

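The settings limma-voom, lists without spelling matches and both outlying libraries at 5 d left out were chosen after seeing the data; the others were planned. With RLE scaling, library totals, no filter, a filter at a CPM of 1 and the replicate block, all 13 gene counts stayed within 1.5 times the values reported. They did so in 10 of 13 cases with DESeq2, 9 with limma-voom and 9 in fits of only the libraries compared. The cause was not tested for any change below.

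Nitrate at 3 h gave 3722 genes in the fit of the compared libraries, 10254 with limma-voom and 3243 with DESeq2, against 1911. At 1 d these settings gave 3, 1854 and 33 against 0, and at 5 d the fit of the compared libraries gave 0 against 6719. The difference between times gave 620, 6593 and 2997, and 4006 without both outlying libraries, against 1335. Rewatered with nitrate at 3 h against drought gave 13687 with limma-voom against 6676.

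With 1 library left out, counts ranged from 401 to 3376 for nitrate at 3 h, 0 to 6 at 1 d and 1789 to 12565 at 5 d, 548 to 3945 for the difference between times, and 3799 to 4809 for 3 h with nitrate against drought; these fits have fewer libraries. They stayed between 33808 and 34614 for drought, and between 9847 and 33309 for the other comparisons with drought, and 23380 and 28197 against well-watered. Drought-raised medians, less the median of all genes, ranged from −0.13 to −0.08 at 3 h, −0.16 to −0.09 at 1 d and −0.42 to −0.12 at 5 d, and drought-lowered ones from 0.14 to 0.2, 0.09 to 0.23 and 0.19 to 0.48.

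With an estimated correlation the drought-raised medians of −0.11, −0.12 and −0.28 and drought-lowered medians of 0.16, 0.17 and 0.34 stayed but no longer passed, and 140 of 142 calls of fixed lists were lost. The replicate block lost 2 of these 142: osmolyte synthesis at 1 d (adjusted p = 0.0678) and jasmonate and defence at 5 d (0.0513). Without spelling matches 7 of 24 list calls were lost, and in 2 others the median did not keep its direction. For proteases at 1 d with nitrate against drought the median fell to 0 from 0.31. For photosystems at 5 d with nitrate against well-watered it changed sign (0.06 against −0.14), with members that the plastid encodes also left out.

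Of 133 values of named genes in fits of only the compared libraries 25 lost their call (all 22 for nitrate at 5 d), and of 810 with 1 library left out 65 did. These totals include genes that the main fit did not call, such as those named at 1 d, which had no call to lose. For the 20 named for nitrate at 3 h, 8, 16 and 7 were called without replicates 1, 2 and 3 without nitrate, and 7, 8 and 20 without those with nitrate. Depth limits the size that can be given for genes at 0 counts in a group, which have only a bound. In simulated data, in which depth was not varied, 41.4% to 48.8% of 2-fold changes were recovered.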

Other observations

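The splits of the nitrate libraries for the drought lists were moved to the fit of all 24 libraries after seeing the result at 5 d, and the shares by genome and the families of product names were added after the data were seen; the other tests were planned.

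In drought 69.9%, 68.8% and 69.6% of the tested genes of the A, B and D genomes were called, 3.7% of each for nitrate at 3 h, and 13%, 12.7% and 13.2% at 5 d; these shares were not tested for a difference, and close copies share reads. Among families of genes with an identical product name, of 66 chlorophyll a-b binding proteins, which carry the light-harvesting pigments, 51 fell and 0 rose, with a median log2 change of −6.09 (adjusted p = 3.63e-11; adjusted p = 0.554 with an estimated correlation), and of 65 peptidylprolyl isomerases, which help proteins fold, 56 fell and 2 rose (adjusted p = 6.55e-10; adjusted p = 0.429 with an estimated correlation).

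The deposited DESeq2 results of the authors and the counts here overlap for drought, with 33777 genes at a deposited q under 0.05, 32130 of them also called here. For nitrate the deposited count was 2523 at 3 h (1305 also called here), 126 at 1 d (0) and 1103 at 5 d (1035). Across genes, which are not independent replicates, the deposited log2 fold changes and those computed here correlated at r = 0.999 for drought and 0.971, 0.964 and 0.999 for nitrate at the 3 times.

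Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In a fit of 6 libraries, splits that mix the groups also put their difference into the spread. A count of 0 in such splits therefore says little about chance. The real count and the highest of the other splits, in fits of 6 libraries, were 34521 and 0 for drought. Against drought they were 16292, 17940 and 21254 without nitrate and 6975, 13995 and 26316 with nitrate, at 3 h, 1 d and 5 d, and against well-watered at 5 d 24723 without and 21772 with nitrate, with a highest other count of 0 in each; 1 of 10 splits reached the real count in each. For the drought-raised genes the real median and the one farthest from 0 among other splits were −0.108 and −0.095 at 3 h, −0.117 and −0.134 at 1 d, and −0.279 and 0.378 at 5 d. For the drought-lowered genes they were 0.163 and 0.07, 0.166 and 0.167, and 0.339 and −0.52. The sign of another split depends on which of its sides is counted as nitrate. At 3 h, 1 d and 5 d 1, 2 and 3 of the 10 splits had a median as far from 0, for both lists.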
